A study of Homo sapiens with 42 samples.

How the data were processed

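The study profiled total RNA of the multiple myeloma line MM.1S by sequencing, per the labels on a NextSeq 500. The 7 groups were an untreated control, for which no treatment time is given, and cells given 100 or 500 nM dBET6 or 500 nM JQ1 for 4 or 18 h. Each group had 3 experiments (13D, 13E and 13F), and each experiment has its own day in the file header. Each experiment and group was sequenced in 2 technical runs, A and B, which makes 42 libraries. The labels call the experiments triplicates. If they are not separate cultures, the p-values measure only the spread between these samples.

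The deposited table holds counts, the raw number of reads per gene and library per the file headers, for 35601 genes named by Ensembl identifiers. Its values are whole numbers and the library totals differ, as was checked in the table. Per the submitters' processing notes the reads were aligned with STAR to hg38 and DESeq2 was used, both without a version. The program that counted reads, the gene annotation, the strandedness and any filter are not given in the sources used here. Gene symbols, coordinates and spans came from GENCODE 29, in which 35486 identifiers were found, and 18 symbols stood on more than 1 identifier. Of 760 symbols in the gene lists 755 were found, older symbols included.

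Libraries held 16717216 to 39075490 counts. Runs A and B of each sample were added, which left 21 samples, and 8126 genes had 0 counts in all libraries. Chi-square per gene between runs A and B, over genes with at least 50 counts, ran from 4.92 to 744, against 142 to 1160 between experiments of a group, so that the runs of some samples differed by much more than counting error. The runs were never used as replicates. In 1 library, run A of the 18 h JQ1 sample of 13D, the title gives JQ1 and the treatment label dBET6. It was grouped by its title, and results without it were computed beside the others.

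Whether the experiment numbers pair the samples was checked with correlations, across 8897 genes at 5 CPM or more, between the residuals of samples of different groups: 34 of 39 same-number correlations were over 0.1 (range -0.155 to 0.949), and the highest with different numbers was 0.48. The numbers were therefore taken as pairing the samples, and a fit with experiments as blocks stands beside the main one, which has no block because the plan was fixed before the data were examined. Also fixed before the data were examined were the groups, the 14 gene comparisons, the tests, the gene lists, the rule for named genes and all alternatives but 2.

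Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3) in a single fit of all 21 samples with 1 coefficient per group, after filterByExpr, which kept 15363 genes, and with TMM factors. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each comparison, and calls of at least 2-fold are counted beside. Adjusted p-values of genes in the text are from edgeR unless another tool is named. Levels are CPM, counts scaled to library totals under TMM factors, and log2 fold changes are edgeR estimates. SE is an approximate standard error, the size of the log2 change divided by the square root of its F statistic. The 95% intervals use it with 14 residual degrees of freedom, without those that edgeR adds by sharing the spread over genes. They are therefore approximate too. Library totals alone replaced TMM factors in an alternative. TMM assumes that most genes do not change, and its factors ran from 0.397 to 1.66.

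The 31 tested gene lists were tested in 13 comparisons with limma 3.58.1 camera (preset correlation 0.01), adjusted over all lists and comparisons, with an estimated correlation and fry beside it. camera compares a list with the other genes. fry tests whether the genes of a list move on balance one way, or in its mixed form either way, and compares them with no other genes. The lists covered BET proteins and P-TEFb regulation, plasma cell and myeloma identity, MAF targets, ribosome biogenesis, other MYC-associated metabolism, G1/S, G2/M, cell cycle inhibitors, histones, p53, BCL2 family, NF-kB, ER chaperones, ATF4, interferon, heat shock, cholesterol synthesis, autophagy and lysosome, immediate early genes, CRL4-CRBN, CRL2-VHL, the COP9 signalosome, the proteasome, cytosolic ribosomal proteins, mitochondrially encoded transcripts, the respiratory chain, long noncoding RNA, and markers of T, myeloid, stromal and epithelial cells. An erythroid list had fewer than 3 measured genes and was not tested. Camera called 134 of 403 list tests, 8 of them also with an estimated correlation, all 8 for histone genes, and fry called 140. In each of the 134 the median, the mean and the test had the same sign.

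Genes were named by a fixed rule. Against the control and between compounds these were the 5 largest rises and 5 largest falls among called genes at 10 CPM or more in the higher group whose samples did not overlap (3 and 3 for dose and time), passing over provisional symbols. A fixed panel of 26 genes and up to 4 members per list with the smallest adjusted p were added. The values of 1 panel gene are not reported here. A first version of the script passed over more symbols than the rule allows and was corrected. Where a group had 0 counts over its samples, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio has an exact counting interval. That interval covers counting error alone, on counts added over the group, and leaves out the spread between samples.

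The gene test was tested on simulated data with the spread of these samples and 200 changed genes per comparison with the control. The first criterion, recovery of more than 4 in 5 of the 4-fold changes, was not met, and the criterion was then changed to unbiased estimates, a mean share of false calls under 10% and recovery of 16-fold changes. edgeR recovered 0% of 1.5-fold, 0 to 4% of 2-fold and 42.1 to 65.3% of 4-fold changes, with 0 to 10.8% false calls. In a second set of 4-fold and 16-fold changes it recovered 64 to 71.1% and 92 to 98.9%, with 2.9 to 5.5% false calls. False calls of DESeq2 made up 12.8 to 29.7%. For 4 h of JQ1 edgeR recovered 0%, 2.9% and 53.4% of 1.5-fold, 2-fold and 4-fold changes. These shares hold for 200 changed genes and the model without blocks. Where more genes change the threshold on unadjusted p is less strict, so smaller changes pass, and neither that case nor the model with experiments as blocks was simulated.

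Alternatives were DESeq2 1.42.0, limma-voom, median-ratio factors, library totals, no expression filter, a filter of 5 CPM in 3 samples, only the groups compared, experiments as blocks, run A or run B alone, fry or an estimated correlation for lists, and leaving out the library with conflicting labels or each sample in turn. After the data were seen, leaving out the 2 samples whose runs differed most (18 h, 500 nM dBET6 of 13F and JQ1 of 13D) and run B of the 4 h 500 nM dBET6 sample of 13F was added. A gene called in neither fit counts as unaltered whatever its sign. Where a sample is left out, the fit over all groups supplies the spread. Correlations of log2 changes between comparisons were set against 5 simulations of unchanged groups compared with the same controls.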

Results

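MM.1S multiple myeloma cells were profiled untreated, after 100 or 500 nM of the BET degrader dBET6 and after 500 nM of the BET bromodomain inhibitor JQ1, for 4 or 18 h. Each group had n = 3 experiments, 13D, 13E and 13F. dBET6 joins a BET ligand to a cereblon ligand so that BET proteins are degraded, whereas JQ1 occupies the bromodomains without degradation. Transcripts of ribosomal proteins made up 11.9 ± 4.48% of all counts in the control (mean ± SD), 29.7 ± 6.95% after 18 h of 100 nM dBET6, 33.5 ± 1.59% after 18 h of 500 nM dBET6 and 17.5 ± 9.25% after 18 h of JQ1. Mitochondrially encoded transcripts made up 5.9 ± 0.185%, 13.2 ± 6.38%, 12.8 ± 6.02% and 8.70 ± 2.59% of counts in the same groups. Genes at 1 CPM or more (counts scaled to the library total) numbered 11529 ± 115 in the control and 9437 ± 195 after 18 h of 500 nM dBET6. Of 35601 genes in the table, 15363 were tested.

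After 4 h of JQ1 the oncogene MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434) fell from 489 ± 60.7 to 69.2 ± 26.3 CPM (mean ± SD, n = 3), a log2 fold change of -2.82 ± 0.60 (SE) with adjusted p = 0.0118. HEXIM1 (ENSG00000186834, chromosome 17, 45148502 to 45152101), which holds the elongation kinase P-TEFb inactive and is a common readout of BET inhibitors, rose from 17.8 ± 2.4 to 94.3 ± 21.5 CPM (2.40 ± 0.30, adjusted p = 0.000248). The chemokine receptor gene CCR1 (ENSG00000163823, chromosome 3, 46201709 to 46208396) fell from 169 ± 48.2 to 12.3 ± 3 CPM (-3.78 ± 0.31, adjusted p = 1.98e-06). The largest rises among genes at 10 CPM or more were HIST1H2AC (log2 4.17), the carboxypeptidase M gene CPM (3.59), SERTAD1 (3.50), IRF7 (3.09) and HIST1H1C (2.90). The largest falls were HEMGN (-3.93), CCR1, TRAT1 (-3.67), CCL3L3 (-3.48) and PLD6 (-3.45). Of 23 histone genes 11 rose and 0 fell (13 rose when adjusted over the list alone), with a list median of 1.75. HIST1H2BJ (4.41), HIST1H2BD (3.55) and HIST1H2BK (2.72) were among them. The list had adjusted p = 2.39e-19 by camera, or adjusted p = 0.00479 with an estimated correlation.

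Genes of plasma cell and myeloma identity moved down after 4 h of JQ1, with 6 of 27 falling and 0 rising (8 over the list alone), median -0.48 and adjusted p = 9.74e-05, against adjusted p = 0.252 with an estimated correlation. CD28 (-1.76), TNFRSF17 (-1.64), TNFRSF13B (-1.48), SLAMF7 (-1.14) and POU2AF1 (-1.05) fell. IRF4 (-0.23, adjusted p = 0.853), PRDM1 (-0.54, adjusted p = 0.603) and XBP1 (-0.48, adjusted p = 0.462) did not pass. CCR1, MAF (-2.53) and NUAK1 (-1.83) were the 3 of 8 MAF targets that fell (3 over the list alone), with adjusted p = 0.00532 for the list and adjusted p = 0.158 with an estimated correlation. Of 39 ribosome biogenesis genes 5 fell, 15 over the list alone (median -0.83, adjusted p = 4.4e-10, adjusted p = 0.508 with an estimated correlation), among them RRS1 (-2.30), WDR43 (-1.91) and POLR1B (-1.53). Of 30 immediate early genes 6 rose and 1 fell (8 and 1 over the list alone), with ZFP36 at 2.51, JUND at 2.30 and DUSP1 at 1.32 and adjusted p = 0.00328, or adjusted p = 0.76 with an estimated correlation. CDK6 (-1.64) and BCL2L1 (-1.01) fell. BRD2 (0.90, adjusted p = 0.428), MCL1 (0.82, adjusted p = 0.495) and CDKN1A (-0.65, adjusted p = 0.707) did not pass. Against the control of the same number, BRD2 and MCL1 were higher in each of the 3 experiments. CDKN1A, IRF4, PRDM1 and XBP1 were lower in each. Their values with experiments as blocks are not given here, so these genes are not shown to be unchanged.

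edgeR called 609 genes after 4 h of JQ1, of which 224 rose and 385 fell, with 215 and 378 of them at least 2-fold and 2451 genes at unadjusted p under 0.05. The count was 381, 255 and 278 without the control of 13D, 13E and 13F, and 293, 189 and 293 without the JQ1 sample of 13D, 13E and 13F. It was 988 without the 18 h 100 nM dBET6 sample of 13F, and 1610 with experiments as blocks. The MYC call was lost without the JQ1 sample of 13E (adjusted p = 0.0849) or 13F (adjusted p = 0.0587). Those of CPM, CCL3L3, HIST1H1C, POU2AF1, MAF, NUAK1, TNFRSF17, TNFRSF13B, SLAMF7, BCL2L1, WDR43, POLR1B and DUSP1 were each lost without at least 1 sample. HEXIM1, CCR1, IRF7, CD28, RRS1, CDK6, ZFP36 and JUND kept theirs in each refit.

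After 4 h of dBET6, MYC fell further than with JQ1, to 6.32 ± 1.79 CPM at 500 nM (-6.27 ± 0.71, adjusted p = 1.2e-05) and 5.99 ± 1.2 CPM at 100 nM (-6.35 ± 0.71, adjusted p = 1.53e-05). HEXIM1 fell, to 9.22 ± 2.5 CPM at 500 nM (-0.95 ± 0.29, adjusted p = 0.0205), and CCR1 fell to 9.18 ± 1.46 CPM (-4.20 ± 0.32, adjusted p = 4.34e-07). Of 27 plasma cell and myeloma identity genes 8 fell and 1 rose at 500 nM (9 and 1 over the list alone), without passing as a list (median -0.12, adjusted p = 0.332). Among them the transcription factor genes XBP1 (-2.62), PRDM1 (-2.13), IRF4 (-2.04), IKZF3 (-1.63) and IKZF1 (-1.46) fell, whereas POU2AF1 (0.28, adjusted p = 0.442) and TNFRSF17 (-0.12, adjusted p = 0.852) did not pass. POU2AF1 was above the control in each of the 3 experiments. The largest rises at 500 nM were EGR1 (9.97 ± 1.31, 261 ± 223 CPM), KIAA1683 (8.26), FOS (6.54), CPM (5.29) and HIST1H2BH (4.12), and at 100 nM EGR1 (8.80), KIAA1683 (7.69), FOS (5.50), CPM (5.37) and TSPOAP1 (3.49). The largest falls at 500 nM were MYC, NFKBIE (-5.73), DUSP5 (-5.36), PELO (-5.23) and RGS1 (-5.23), and at 100 nM MYC, NFKBIE (-5.60), DUSP5 (-5.28), SGK1 (-5.07) and DUSP4 (-4.82).

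**Figure D1:**
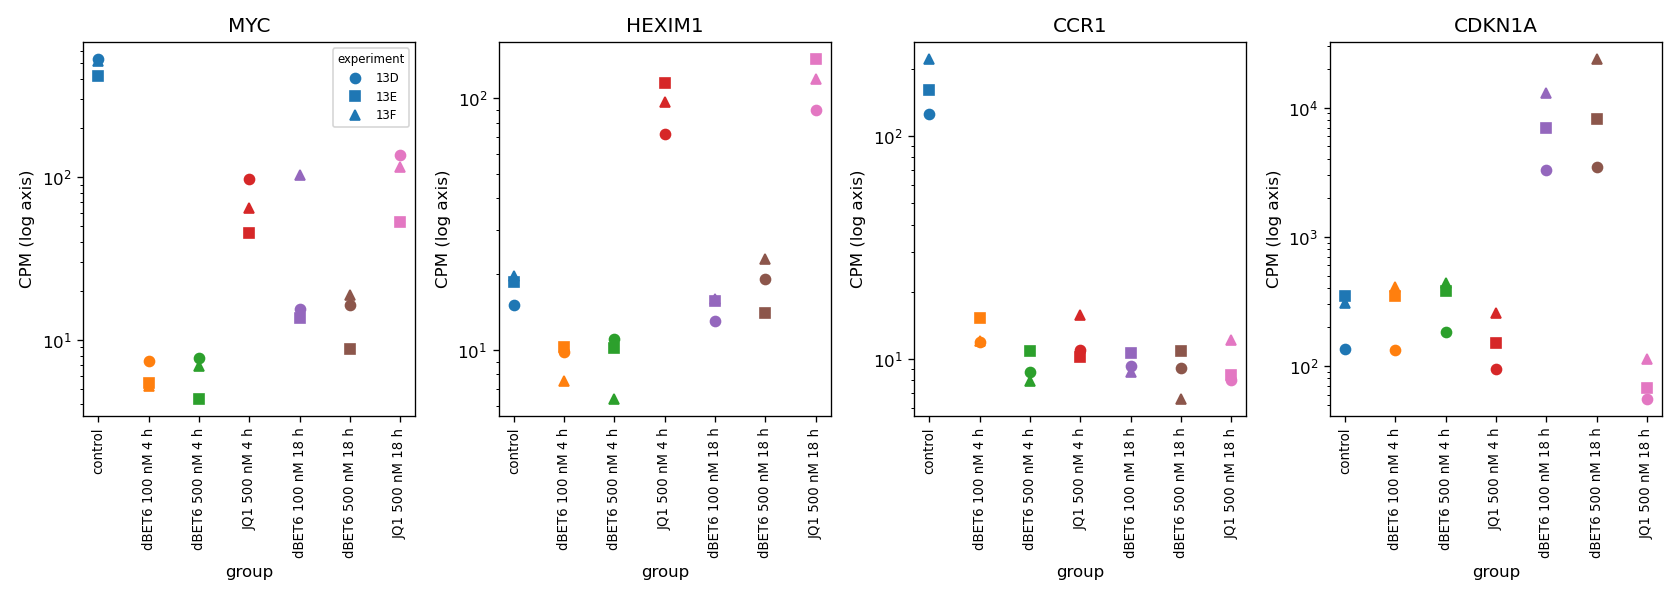
CPM of MYC, HEXIM1, CCR1 and CDKN1A (log axis) in the control and the treated groups, 1 point per sample and n = 3 per group. HEXIM1 lay at 94.3 CPM after 4 h of JQ1 and at 9.22 CPM after 4 h of 500 nM dBET6, against 17.8 CPM in the control.

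Genes for BET proteins and P-TEFb regulation fell after 4 h of 500 nM dBET6, 9 of 22 with 0 rising (13 over the list alone), median -1.21 and adjusted p = 0.00233, or adjusted p = 0.765 with an estimated correlation. ELL (-2.69), MEPCE (-2.39), BRD3 (-1.69) and NELFA (-1.58) fell, whereas BRD2 (-1.13, adjusted p = 0.117) did not pass. BRD2 passed with experiments as blocks (-1.21, adjusted p = 0.00019). Of 39 ribosome biogenesis genes 15 fell (15 over the list alone, median -0.87, adjusted p = 1.97e-05, adjusted p = 0.724 with an estimated correlation), with RRS1 at -3.46, WDR43 at -3.40 and POLR1B at -3.03. Of 30 immediate early genes 4 rose and 11 fell (4 and 11 over the list alone), with PIM1 at -2.99, and the list did not pass (median -0.30, adjusted p = 0.0863). Among 18 BCL2 family genes BBC3 (-2.90), BMF (-2.49), MCL1 (-1.77), BCL2L11 (-1.65) and BCL2L1 (-1.09) fell, 6 in all with 0 rising (7 and 1 over the list alone), and the list did not pass (adjusted p = 0.382). Of 26 NF-kB targets 8 fell and 0 rose (9 and 1 over the list alone, median -0.60, adjusted p = 0.0202, adjusted p = 0.807 with an estimated correlation). AURKA (-2.42) was among the 9 of 32 G2/M genes that fell (9 over the list alone, adjusted p = 0.0195, adjusted p = 0.835 with an estimated correlation). Without the dBET6 sample of 13D that list had adjusted p = 0.0917. Histone genes rose again, 13 of 23 with 0 falling (16 over the list alone), with HIST1H3H at 3.78 and HIST1H2BD at 3.82. The list had median 1.95 and adjusted p = 2.49e-10, or adjusted p = 0.0448 with an estimated correlation.

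edgeR called 3450 genes after 4 h of 500 nM dBET6 (994 rose and 2456 fell, 849 and 2332 at least 2-fold) and 2882 after 100 nM (741 and 2141, 658 and 2049 at least 2-fold). With library totals in place of TMM factors the median of all genes at 500 nM moved from 0.08 to -0.31, and 515 genes rose and 3175 fell. Without the dBET6 sample of 13E the counts were 2233 at 500 nM and 1607 at 100 nM. At 100 nM they were 1873 without the dBET6 sample of 13F, 1903 without the control of 13F, and 4840 with experiments as blocks (5822 at 500 nM). The call of HEXIM1 at 500 nM was lost without the control of 13E (adjusted p = 0.0651) or 13F (adjusted p = 0.0819) or the dBET6 sample of 13F (adjusted p = 0.108). That of MCL1 was lost without at least 1 sample.

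After 18 h of JQ1, MYC stood at 102 ± 43.6 CPM (-2.26 ± 0.59, adjusted p = 0.0131), HEXIM1 at 117 ± 26.5 CPM (2.72 ± 0.30, adjusted p = 1.38e-05) and CCR1 at 9.53 ± 2.25 CPM (-4.15 ± 0.32, adjusted p = 5.18e-07). Genes of DNA replication, which are induced by E2F as cells enter S phase, fell together. They fell in 25 of 36 G1/S genes and rose in 0 (34 over the list alone), with CDC6 at -2.59, E2F1 at -2.11, CCNE1 at -1.97 and GINS1 at -1.77. That list had median -1.62 and adjusted p = 4.04e-13, or adjusted p = 0.577 with an estimated correlation. Of 39 ribosome biogenesis genes 26 fell (34 over the list alone, median -1.62, adjusted p = 1.99e-14, adjusted p = 0.396 with an estimated correlation). Of 26 other MYC-associated metabolic genes 15 fell (18 over the list alone, median -1.32, adjusted p = 2.51e-08, adjusted p = 0.443 with an estimated correlation). The largest rises were DHRS2 (5.80), HIST1H2BD (4.93), HIST1H1C (4.61), HIST1H2AC (4.10) and SYT11 (4.08). The largest falls were HEMGN (-6.77), DDN (-5.03), BHLHA15 (-4.84), PYCR1 (-4.46) and ACSL5 (-4.44).

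Of 27 plasma cell and myeloma identity genes 12 fell and 0 rose after 18 h of JQ1 (15 over the list alone), with TNFRSF17 at -3.28, TNFRSF13B at -2.61, POU2AF1 at -1.37, CD28 at -1.31 and XBP1 at -1.10. The list had median -0.99 and adjusted p = 3.83e-05, or adjusted p = 0.217 with an estimated correlation. IRF4 (-0.54, adjusted p = 0.371), PRDM1 (0.11, adjusted p = 0.896) and IKZF1 (-0.61, adjusted p = 0.21) did not pass. IKZF1 was below the control in each of the 3 experiments. Of 23 cell cycle inhibitors 5 rose and 0 fell (11 and 1 over the list alone), with BTG2 at 2.24, MXD4 at 2.18 and CDKN2D at 1.94 and adjusted p = 0.000191, or adjusted p = 0.327 with an estimated correlation. CDKN1A did not pass (78.6 ± 30.6 CPM, -1.74 ± 0.65, adjusted p = 0.0774), although it did with experiments as blocks (-1.69, adjusted p = 0.000584). Of 27 ER chaperone genes 9 fell (10 over the list alone, median -0.63, adjusted p = 0.000122, adjusted p = 0.628 with an estimated correlation), with PDIA4 at -1.24 and CANX at -1.03. MCL1 rose by 1.72 and SERPINI1 by 2.54. Of the histone genes 16 of 23 rose (20 over the list alone, median 2.47, adjusted p = 3.87e-15, adjusted p = 0.00871 with an estimated correlation). edgeR called 2227 genes (758 rose and 1469 fell, 676 and 1396 at least 2-fold). It called 1234, 1301 and 1119 without the control of 13E, the control of 13F and the JQ1 sample of 13E, and 4081 with experiments as blocks. Without that JQ1 sample MYC (adjusted p = 0.0818) and E2F1 (adjusted p = 0.051) lost their calls, and MCL1, BTG2, XBP1 and CANX lost theirs without at least 1 sample.

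After 18 h of 500 nM dBET6 the transcripts were reshaped much more widely. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), the p53-inducible inhibitor of cyclin-dependent kinases, rose from 262 to 11700 ± 10500 CPM (5.48 ± 0.76, adjusted p = 9.99e-06). It stood at 7740 ± 4930 CPM at 100 nM (4.88 ± 0.74, adjusted p = 5.86e-05). MYC fell to 14.6 ± 5.27 CPM at 500 nM (-5.06 ± 0.67, adjusted p = 6.52e-06) and to 44 ± 50.9 CPM at 100 nM (-3.47 ± 0.62, adjusted p = 0.000245). At 100 nM MYC stood at 15.5 and 13.6 CPM in 13D and 13E and at 102.8 CPM in 13F, and without the latter sample the change was -4.94. CCR1 fell to 8.84 ± 2.12 CPM (-4.25 ± 0.32, adjusted p = 3.16e-08). HEXIM1 did not pass at 500 nM (18.7 ± 4.53 CPM, 0.07 ± 0.28, adjusted p = 0.846). The largest rises at 500 nM were RRAD (14.74, 8520 ± 8730 CPM), ARC (14.12) and KIAA1683 (13.99). MUC2 had 2 counts over the 3 controls (ratio 7640, counting interval 2110 to 63100), and CILP had 0 counts in the controls and rose at least 920-fold. The counting interval of MUC2 leaves out the spread between samples. At 100 nM the largest rises were RRAD (13.74), KIAA1683 (13.20), ARC (12.88), MUC2 at 41 ± 53.5 CPM and EGR1 (11.54). The largest falls were NUAK1 (-5.88), SQLE (-5.72), ABHD17C (-5.67), PPRC1 (-5.65) and CDC25A (-5.63) at 500 nM, and SQLE (-4.62), CCDC86 (-4.52), CXCR3 (-4.45), CCR1 (-4.15) and MYB (-4.13) at 100 nM.

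Histone genes had the largest list median after 18 h of dBET6: 22 of 23 rose and 0 fell at each dose, adjusted over all genes or over the list alone. The medians were 6.63 at 500 nM (adjusted p = 1.94e-15, adjusted p = 0.00871 with an estimated correlation) and 6.24 at 100 nM. HIST1H2BG (8.91), HIST1H2BD (8.27), HIST1H2BK (7.21) and HIST1H3H (6.80) rose at 500 nM. All 62 cytosolic ribosomal protein genes rose at each dose, also over the list alone (median 3.14 at 500 nM, adjusted p = 2.39e-19, adjusted p = 0.72 with an estimated correlation, and median 2.58 at 100 nM). RPS12 rose by 3.95 and RPLP1 by 3.69. All 15 mitochondrially encoded transcripts rose at 500 nM (15 over the list alone, median 2.56, adjusted p = 4.25e-06, adjusted p = 0.711 with an estimated correlation), MT-RNR2 by 4.28 and MT-CO2 by 2.80. These transcripts made up 27.42% of run B and 9.34% of run A of the 500 nM sample of 13F, and without that sample MT-RNR2 rose by 3.54, MT-CO2 by 2.26 and the list had adjusted p = 3.96e-05. Of 30 immediate early genes 16 rose and 6 fell (16 and 6 over the list alone, median 1.55, adjusted p = 0.00906, adjusted p = 0.791 with an estimated correlation), with JUN at 6.53, JUND at 4.25, DUSP1 at 3.98 and PIM1 at -3.22. Without the 500 nM sample of 13F the immediate early list had adjusted p = 0.0623. Ribosome biogenesis genes fell, 29 of 39 with 1 rising (30 and 2 over the list alone, median -2.01, adjusted p = 8.14e-06, adjusted p = 0.724 with an estimated correlation), with RRS1 at -4.27 and POLR1B at -4.09.

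Of 26 p53 targets 10 rose and 6 fell after 18 h of 500 nM dBET6 (10 and 6 over the list alone), MDM2 (3.93), BBC3 (3.64), DDB2 (3.03) and FDXR (2.40) among those that rose. The list as a whole did not pass (median 0.74, adjusted p = 0.222). Of 27 plasma cell and myeloma identity genes 15 fell and 6 rose (15 and 6 over the list alone), with TNFRSF17 at -3.23, IKZF1 at -3.11, IKZF3 at -2.07 and CD28 at -1.86, without passing as a list (adjusted p = 0.147). IRF4 (-0.76, adjusted p = 0.092), POU2AF1 (-0.43, adjusted p = 0.161) and MAF (-1.24, adjusted p = 0.101) did not pass, and IRF4 passed with experiments as blocks (-0.82, adjusted p = 0.0151). POU2AF1 and MAF were lower than the control in each of the 3 experiments. These values hold under TMM factors, which ran from 1.452 to 1.554 in the control and from 0.397 to 0.517 in this group. Library totals therefore place IRF4, POU2AF1 and MAF further below the control, by values not given here. In the BET and P-TEFb list CDK12 (-3.69), ELL2 (-2.97), NELFA (-2.77) and BRD3 (-2.34) fell, 11 of 22 with 2 rising (12 and 2 over the list alone, list adjusted p = 0.0769). ATF3 (6.29), DDIT3 (4.88) and NFKBIA (3.17) rose, whereas BMF (-4.81), CDK6 (-3.46) and BCL2L1 (-1.21) fell.

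**Figure D2:**
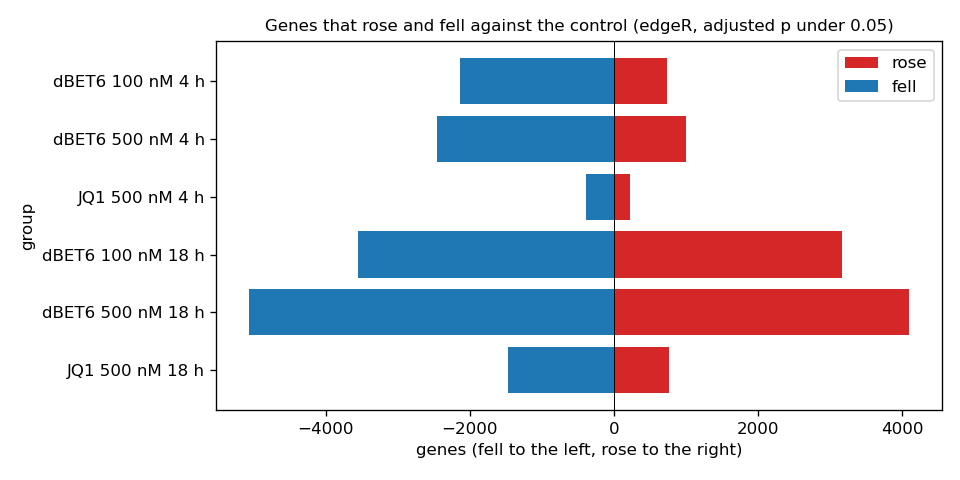
Number of genes called against the control (adjusted p under 0.05 in edgeR) in each treated group, rises and falls as separate bars, n = 3 per group. The counts ran from 224 rises and 385 falls after 4 h of JQ1 to 4094 rises and 5058 falls after 18 h of 500 nM dBET6.

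edgeR called 9152 genes after 18 h of 500 nM dBET6 (4094 rose and 5058 fell, 3823 and 4663 at least 2-fold) and 6705 after 100 nM (3160 and 3545, 2942 and 3142 at least 2-fold). The latter count was 4054 under the stricter filter and 4118 with only the 2 groups fitted. With library totals in place of TMM factors the median of all genes moved from -0.14 to -1.85 at 500 nM and from -0.15 to -1.36 at 100 nM. The split became 1366 rises and 9879 falls at 500 nM and 1305 and 8688 at 100 nM. Of the named genes called with TMM, directions then flipped at 500 nM for ACTB (1.67 to -0.07) and PDIA4 (1.32 to -0.41). BRD2 (-1.46), HEXIM1 (-1.66), MCL1 (-1.37), BCL2 (-1.56) and E2F1 (-1.51), above 0 and not called with TMM, passed as lower. Among the medians that flipped were those of ER chaperones (0.66 to -1.12), the respiratory chain (1.52 to -0.14), immediate early genes (1.55 to -0.14), p53 targets (0.74 to -1.0), ATF4 targets (0.61 to -1.15), autophagy and lysosome (0.73 to -0.97), the proteasome (0.45 to -1.24) and cell cycle inhibitors (0.41 to -1.26). Histone (4.85), ribosomal protein (1.41) and mitochondrially encoded (0.79) medians stayed above 0 and ribosome biogenesis (-3.72) stayed below 0 at 500 nM. No spike-in was used here, so neither scaling gives an amount per cell. Histone and ribosomal protein genes and CCL3L3 have near-identical copies, so counts of single members depend on how shared reads were assigned.

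**Figure D3:**
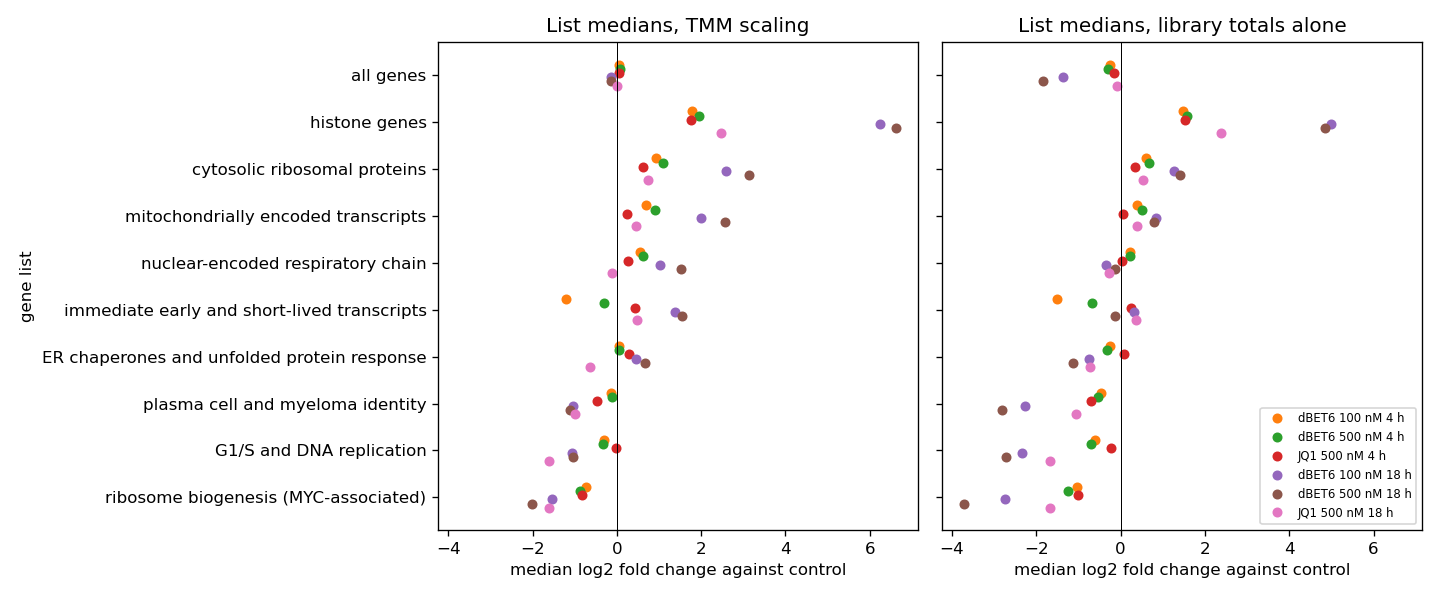
Median log2 fold change of all genes and of a selection of the gene lists against the control under TMM factors and under library totals, 1 point per entry, comparison and scaling. After 18 h of 500 nM dBET6 the ribosomal protein median was 3.14 under TMM and 1.41 under library totals, and the ER chaperone median moved from 0.66 to -1.12.

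Set directly against JQ1 at 4 h, 500 nM dBET6 left HEXIM1 lower (9.22 ± 2.5 against 94.3 ± 21.5 CPM, -3.35 ± 0.31, adjusted p = 2.45e-06) and MYC lower (6.32 ± 1.79 against 69.2 ± 26.3 CPM, -3.45 ± 0.62, adjusted p = 0.000534). Of 22 BET and P-TEFb genes 12 were lower and 0 higher under dBET6 (14 over the list alone, median -1.39, adjusted p = 0.000195, adjusted p = 0.724 with an estimated correlation), with MEPCE at -3.25, BRD3 at -2.42 and BRD2 at -2.02. IRF4 (-1.82), PRDM1 (-1.59) and XBP1 (-2.14) were lower under dBET6, whereas the surface receptor genes SLAMF7 (1.59), TNFRSF17 (1.53) and CD28 (1.52) and POU2AF1 (1.33) were higher. Immediate early genes were lower, 14 of 30 with 2 higher (14 and 2 over the list alone, median -1.32, adjusted p = 0.000198, adjusted p = 0.711 with an estimated correlation), with PIM1 at -3.27. MCL1 (-2.59) and BCL2L11 (-2.06) were lower and CDK6 higher (1.01). CCR1 did not pass (-0.42, 95% interval -1.03 to 0.18). The largest differences were EGR1 (6.38), KIAA1683 (6.17), FOS (4.80), ASB2 (2.91) and HIST1H2BH (2.90) upward. Downward they were NFKBIE (-5.61), IRF1 (-5.14), DUSP5 (-5.13), GPATCH3 (-5.13) and VPS18 (-5.00). edgeR called 3670 genes (1163 higher and 2507 lower under dBET6), 2294 without the dBET6 sample of 13E and 5535 with experiments as blocks. The calls of PRDM1, BRD2, CDK6 and TNFRSF17 were each lost without at least 1 sample.

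At 18 h CDKN1A stood at 11700 ± 10500 CPM under 500 nM dBET6 and 78.6 ± 30.6 CPM under JQ1 (7.22 ± 0.83, adjusted p = 1.82e-06), and HEXIM1 at 18.7 ± 4.53 and 117 ± 26.5 CPM (-2.65 ± 0.30, adjusted p = 1.71e-06). MYC (-2.80), IKZF1 (-2.50), IKZF3 (-2.05), BRD3 (-3.07), ELL2 (-3.62) and CDK6 (-2.10) were lower under dBET6, whereas E2F1 (2.35), POU2AF1 (0.94), ATF3 (5.51), DDIT3 (3.49) and BBC3 (2.66) were higher. TNFRSF17 (0.05, adjusted p = 0.922), XBP1 (-0.01, adjusted p = 0.985) and CCR1 (-0.11, adjusted p = 0.758) did not pass. Histone genes were higher, 21 of 23 (21 over the list alone, median 3.46, adjusted p = 6.13e-09, adjusted p = 0.0591 with an estimated correlation). So were ER chaperone genes, 17 of 27 with 1 lower (17 and 1 over the list alone, median 1.48, adjusted p = 0.00148, adjusted p = 0.724 with an estimated correlation). The largest differences upward were MUC2 (1 count over the 3 JQ1 samples, ratio 14300, counting interval 2560 to 564000), ASTL (0 counts, at least 1480-fold), VGF (13.05), LYZ (3 counts, ratio 9670, counting interval 3310 to 46900) and KIAA1683 (12.93). Neither counting interval includes the spread between samples. Downward they were BMF (-6.37), TGFBR2 (-5.39), SNX20 (-5.37), CCDC102A (-5.37) and ILDR1 (-5.29). edgeR called 9562 genes (4578 higher and 4984 lower). With library totals the median of all genes moved from -0.10 to -1.72 and the split to 1684 and 9264. The medians of ER chaperones (1.48 to -0.11), G1/S genes (0.46 to -1.18), p53 targets (1.26 to -0.48), immediate early genes (1.21 to -0.29) and the proteasome (0.76 to -0.81) and the direction of POU2AF1 (-0.73) flipped. TNFRSF17 (-1.40), CCND2 (-1.63) and BRD2 (-1.71), above 0 and not called with TMM, passed as lower. XBP1 and CCR1, below 0 and not called with TMM, also lie lower under dBET6 with library totals, by values not given here.

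Between the 2 doses of dBET6 at 4 h, MYC differed by 0.08 (95% interval -1.14 to 1.30), HEXIM1 by 0.00 (-0.61 to 0.61), XBP1 by -0.34 (-0.95 to 0.28) and CCR1 by -0.51 (-1.11 to 0.10). CCR1 and XBP1 were lower at 500 nM in each of the 3 experiments, and with experiments as blocks edgeR called 0 genes (159 at unadjusted p under 0.05, CCR1 at -0.50). edgeR called 0 genes at 4 h, with 97 at unadjusted p under 0.05, DESeq2 called 0 (150 unadjusted), limma-voom 0 (57 unadjusted), and edgeR without the expression filter 38. By camera 8 of 31 lists differed between doses at 4 h, each with a call lost without 1 sample and none called with an estimated correlation. Ribosome biogenesis (median -0.15, adjusted p = 2.72e-05, adjusted p = 0.724 with an estimated correlation, 0.895 without the 500 nM sample of 13D) and BET and P-TEFb genes (-0.13, adjusted p = 0.0066, adjusted p = 0.791 with an estimated correlation, 0.207 without the 100 nM sample of 13F) were lower at 500 nM. Higher were histones (0.13, adjusted p = 0.000993, adjusted p = 0.396 with an estimated correlation, 0.616 without the 100 nM sample of 13D) and immediate early genes (0.23, adjusted p = 0.000993, adjusted p = 0.724 with an estimated correlation, 0.0836 without the 100 nM sample of 13F). So were ribosomal proteins (0.17, adjusted p = 0.00978, adjusted p = 0.9 with an estimated correlation, 0.131 without the 100 nM sample of 13F) and mitochondrially encoded transcripts (0.19, adjusted p = 0.0244, adjusted p = 0.835 with an estimated correlation, 0.746 without the 100 nM sample of 13D). The other 2, also higher, were stromal (adjusted p = 3.63e-07, adjusted p = 0.117 with an estimated correlation, 0.481 without the 500 nM sample of 13F) and epithelial markers (adjusted p = 7.6e-08, adjusted p = 0.0591 with an estimated correlation, 0.54 without that sample). At 18 h, 2 genes rose and 518 fell with dose, CSTF1 (-3.86, adjusted p = 0.017), CPTP (-3.65) and CWC22 (-3.40) falling most. limma-voom called 0 genes (2200 unadjusted) and edgeR with only the 2 groups fitted 0 (910 unadjusted), whereas DESeq2 called 1015, edgeR with experiments as blocks 1041 and with library totals 2027. BMF (-3.33), ELL (-1.98), ELL2 (-1.57) and NELFA (-1.46) were lower at 500 nM. MYC (-1.59, 95% interval -2.84 to -0.35, adjusted p = 0.144) and CDKN1A (0.60, adjusted p = 0.679) did not pass. Of 22 BET and P-TEFb genes 4 fell with dose at 18 h (7 over the list alone, median -0.85, adjusted p = 0.000756, adjusted p = 0.73 with an estimated correlation). Without the 100 nM sample of 13F the list had adjusted p = 0.0778. The 520 calls at 18 h rested on single samples: 5 genes were called without the 100 nM sample of 13F and 0 without the 500 nM sample of 13D or that of 13E. In turn 1655 and 1033 were called without the 100 nM samples of 13D and 13E. In the 100 nM sample of 13F, CSTF1 stood at 35.2 CPM, against 2.6 and 8.1 CPM in the other 2.

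Between 4 and 18 h of 500 nM dBET6 the fall of IRF4, PRDM1 and XBP1 was partly undone under TMM scaling. IRF4 rose by 1.29, PRDM1 by 1.71 and XBP1 by 1.51 from their 4 h levels, MCL1 by 2.20 and HEXIM1 by 1.02. With library totals these rises did not pass for XBP1 (0.21, adjusted p = 0.472) and PRDM1 (0.33, adjusted p = 0.571), so they depended on the scaling. Without the 18 h sample of 13F IRF4 (0.70, adjusted p = 0.156) and MCL1 (1.17, adjusted p = 0.0599) did not pass, nor did IRF4 without the 4 h sample of 13E (adjusted p = 0.0529) or HEXIM1 without that of 13F (0.80, adjusted p = 0.0649). TNFRSF17 (-3.11), CDK6 (-2.82) and IKZF1 (-1.66) fell only or further at 18 h, and CDKN1A rose by 5.13. MYC did not pass at 500 nM (1.21, 95% interval -0.03 to 2.45, adjusted p = 0.109) but rose at 100 nM (2.88, adjusted p = 0.00258). Without the 18 h 100 nM sample of 13F the values were 1.31 (adjusted p = 0.027) at 100 nM and 1.20 (adjusted p = 0.0164) at 500 nM, so the contrast between doses rested on that sample. Immediate early genes rose with time at 500 nM, 21 of 30 with 0 falling (22 over the list alone, median 2.56, adjusted p = 5.26e-10, adjusted p = 0.387 with an estimated correlation). The largest changes over time were MUC2 from 0.0135 to 69.4 CPM, VGF (10.90) and LCE1C from 0.0151 to 23.8 CPM upward and SQLE (-4.71), CXCR3 (-3.96) and PUDP (-3.89) downward at 500 nM. For MUC2 and LCE1C these are group means, given without the spread between samples. At 100 nM they were VGF (11.13), MUC2 (10.14), RRAD (9.88), SQLE (-3.66), CXCR3 (-3.50) and SLAMF6 (-3.27). Under TMM scaling edgeR called 5503 genes at 500 nM (2679 rose and 2824 fell) and 3582 at 100 nM (2090 and 1492). The latter count was 2221 without the 4 h sample of 13E and 1338 with only the 2 groups fitted. With library totals the counts were 9137 and 6702, and IRF4 (-0.07), HEXIM1 (-0.29), GAPDH (-0.05) and ACTB (-0.58) at 500 nM changed direction. Library totals lower all genes at 18 h relative to 4 h of dBET6, so the split into rises and falls depends on the scaling. That split with library totals is not given here.

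Between 4 and 18 h of JQ1, genes of DNA replication fell, 15 of 36 G1/S genes with 0 rising (32 over the list alone, median -1.68, adjusted p = 6.75e-20, adjusted p = 0.396 with an estimated correlation), with E2F1 at -2.11. TNFRSF17 fell by 1.64, whereas MYC (0.56, 95% interval -0.65 to 1.77) and HEXIM1 (0.32, -0.29 to 0.92) did not pass. Of 27 ER chaperone genes 11 fell (18 over the list alone, median -1.03, adjusted p = 1.3e-11, adjusted p = 0.217 with an estimated correlation). SYT11 (2.80), TRANK1 (2.73) and SAMD9L (2.19) rose most, and HBD (-4.22), CRYBB1 (-3.91) and SLC38A5 (-3.81) fell most. edgeR called 632 genes (161 rose and 471 fell). The count was 402, 290 and 282 without the 4 h JQ1 sample of 13D, 13E and 13F, and 140 and 343 without the 18 h JQ1 sample of 13E and 13F. It was 999 without the 18 h 100 nM dBET6 sample of 13F, 950 without the library with conflicting labels, and 1883 with experiments as blocks. The calls of E2F1, TNFRSF17 and TRANK1 were each lost without at least 1 sample.

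Under TMM scaling the difference between 500 nM dBET6 and JQ1 itself changed from 4 to 18 h in 3878 genes, 2010 upward and 1868 downward. CDKN1A gained 6.22 ± 0.96 (adjusted p = 0.000348), E2F1 2.39 ± 0.68 (adjusted p = 0.0162), XBP1 2.13 ± 0.41 (adjusted p = 0.00146), BRD2 2.08 ± 0.72 (adjusted p = 0.0396) and IRF4 1.60 ± 0.54 (adjusted p = 0.0349). CDK6 lost ground under dBET6 (-3.12 ± 0.42, adjusted p = 0.000109), as did IKZF1 (-1.94 ± 0.45, adjusted p = 0.0049) and IKZF3 (-1.59 ± 0.52, adjusted p = 0.0305). HEXIM1 (0.71, 95% interval -0.15 to 1.56), MYC (0.65, -1.07 to 2.37) and CCR1 (0.32, -0.54 to 1.17) did not pass. The count ran from 2641 to 5050 when 1 sample was left out, and was 6893 with library totals and 6015 with experiments as blocks. TMM factors of 500 nM dBET6 were 1.026 to 1.217 at 4 h and 0.397 to 0.517 at 18 h. Those of JQ1 were 1.116 to 1.396 and 1.088 to 1.66. Library totals therefore shift all these differences downward, so the gains of E2F1, XBP1, BRD2 and IRF4 depend on the scaling. Values of single genes and the split with library totals are not given here. The calls of E2F1, BRD2, IRF4 and IKZF3 were each lost without at least 1 sample.

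Across 15363 genes the log2 changes after 4 h of 500 nM dBET6 and of JQ1 correlated with r = 0.367 (covariance 0.452), against r = 0.495 (covariance 0.126) in 5 simulations in which only the shared controls linked the 2 comparisons. Both compounds raised 80 genes, against 14.5 for independent calls, and lowered 163, against 61.5. The 12 genes called in opposite directions, HEXIM1 among them, were all lower under dBET6 and higher under JQ1. At 18 h r was 0.242 (covariance 0.647), against a simulated r = 0.472 (covariance 0.126), so at both times r lay below and the covariance above the simulated value. At that time 365 genes rose and 593 fell under both (202 and 483.6 for independent calls). Another 332 were opposite under TMM scaling, 256 of them higher under dBET6 and lower under JQ1 and 76 the reverse. The 2 doses of dBET6 had r = 0.959 at 4 h (simulated 0.486) and 0.941 at 18 h (simulated 0.457). Between 4 and 18 h r was 0.787 for 500 nM dBET6 (simulated 0.468), 0.713 for 100 nM (simulated 0.477) and 0.656 for JQ1 (simulated 0.505). These values run across genes, which are not independent replicates. The simulations drew each sample independently, with the spread of the fit without blocks. They left out the experiment effects that link samples of the same number, so the simulated values are not an exact reference. Simulations with such effects were not run. The 3 controls shared by the comparisons, too few to divide, raise the overlap above that of independent calls.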

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

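The tests of scaling, marker transcripts, mixed RNA and a wrong label, and the fits without the 2 samples whose runs differed most or without 1 technical run, were chosen after the result was seen. The tests of genomic DNA and of other splits of the samples were not.

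The contrast between degrader and inhibitor differed by time, which the test of that difference flagged for a closer look: 3878 genes changed their difference between 500 nM dBET6 and JQ1 from 4 to 18 h in edgeR. Of 100 splits that exchanged samples of the 2 compounds within each time, 9 called as many, the real one included, so chance is not excluded by this count, and the highest other called 7038. The other 8 left the 18 h samples in their groups and exchanged samples only at 4 h, so they keep the difference at 18 h. No split that exchanged 18 h samples called as many. Such an exchange mixes 2 groups that differed in 9562 genes and widens the spread within each side. Few calls were therefore to be foreseen there, and those splits do not bear on whether the difference changed with time. Another difference between compounds is the sign of a response. At 4 h 12 genes were called in opposite directions against the control with the difference itself called, and at 18 h 332 were. Both counts use TMM scaling. With library totals fewer genes rose after 18 h of 500 nM dBET6, so the count at 18 h depends on the scaling, and its value with library totals is not given here. HEXIM1 was among the 12, with dBET6 minus JQ1 at -3.35 on the log2 scale.

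In each comparison of 3 against 3 samples the 10 splits are too few for a share under 0.05. The real split alone (1 of 10) gave the count against the control for 4 h of 100 nM dBET6 (2882), 500 nM dBET6 (3450) and JQ1 (609) and 18 h of 100 nM dBET6 (6705), 500 nM dBET6 (9152) and JQ1 (2227). So it did between compounds at 4 h (3670) and 18 h (9562) and over time for 100 nM dBET6 (3582), 500 nM dBET6 (5503) and JQ1 (632). The highest other split called 0 genes in each of these 11 comparisons by edgeR. Each other split mixes both groups on each side and widens the spread within it. Few calls were therefore to be foreseen, and these 0 calls do not bear on whether chance gave the real counts. For dose at 4 h all 10 splits, the real one included, called 0, with 97 genes at unadjusted p under 0.05 in the real one and 0 calls by DESeq2 or limma-voom. For dose at 18 h 2 of 10 splits called 520 or more. The highest other, 3404 genes, had both 13F samples on 1 side together with a 100 nM sample of 13E, which points to a structure of the samples beside dose. With experiments as blocks the count for dose at 18 h was 1041.

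Ribosomal protein, mitochondrially encoded and histone transcripts were higher after 18 h of dBET6. TMM scaling alone does not account for it, because with library totals the ribosomal protein median at 500 nM was still 1.41, against 3.14 with TMM. Reads from genomic DNA would cover silent genes as well, but only 3.8% of the 14563 genes with 0 counts in all controls had counts in all 3 samples of 18 h of 500 nM dBET6. After 18 h of JQ1 the share was 0.6%. Counts in none of the 3 samples were found for 78.4% and 87.8% of these genes. This goes against genomic DNA that covers most silent genes. A low level would leave many of them without counts, so it stays open. Whether the other transcripts fell in amount per cell under dBET6 was not tested, since no table holds such an amount. Reads shared between near-identical copies also stay open.

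In the 4 h 500 nM dBET6 sample of 13F, epithelial and stromal transcripts stood apart. Run B held KRT8 at 32.4 CPM and KRT18 at 17.7 CPM, run A 0 and 0.23 CPM, and 11 genes of the summed sample lay 20-fold above all other samples, against 0 genes in each of the other samples. If both runs drew on the same culture, other cells in it would show in both, but 0 of the 6 measured epithelial markers did. Whether they drew on the same culture was not tested, so other cells in the source of run B alone stay open. Foreign RNA or reads in 1 technical run may be the source, since 5 of the 6 were more than 3 times higher in run B than in run A and in the other 4 h samples of 13F. This test replaced an earlier one for both runs after the levels per run were seen, and whether library preparation or sequencing added the reads was not tested.

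The 18 h 100 nM dBET6 sample of 13F lay nearer to the control than the other 2 of its group, and without it dose at 18 h gave 5 genes. By correlation alone it would be taken as mislabelled: its highest Spearman correlation with an 18 h dBET6 group was below its highest with another group by a difference of -0.105 (0.753 against 0.857 with 4 h of JQ1, and 0.792 with the control). A second test, chosen after the first had come out so, argues against a wrong label: 19 genes stood over 8-fold above all other groups in each of the other 5 dBET6 18 h samples, and 100% of them did in this sample. A mixture with untreated RNA would give every gene 1 share of control, and over genes chosen without this sample the median share was 0.16 over 1181 lowered and -0.51 over 40 raised genes, a difference of 0.67, but in the 500 nM sample of 13F the medians were 0 and -0.72, so the raised genes differ between experiments and a mixture stays open (this test replaced one on genes chosen by the dose calls, which this sample largely decides). No biological explanation was tested.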

How the results depend on the processing

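The fits without the 2 samples whose runs differed most and without 1 run with epithelial transcripts were added after the result was seen. The cause of a change was not tested unless fewer genes or samples give it. Against the control, the count for 4 h of 100 nM dBET6 was 1897 with the filter at 5 CPM and 4840 with experiments as blocks, and for 500 nM 5822 with blocks. For 4 h of JQ1 it was 1152 with DESeq2, 1189 with only the groups compared, 1610 with blocks and 237 from run A alone. After 18 h it was 4054 (filter at 5 CPM) and 4118 (only the groups) for 100 nM dBET6, and 1365 (filter) and 4081 (blocks) for JQ1. Between compounds at 4 h it was 5535 with blocks. Dose at 4 h gave 38 genes with no filter. Dose at 18 h gave 1015 with DESeq2, 0 with limma-voom, 2027 with library totals, 1178 with no filter, 280 with the filter at 5 CPM, 0 with only the groups compared, 1041 with blocks, 226 from run B and 812 without the 2 samples. Over time the counts were 6702 (library totals), 1338 (only the groups) and 5461 (blocks) for 100 nM dBET6 and 9137 (library totals) for 500 nM. For JQ1 over time they were 1228 (DESeq2), 408 (filter at 5 CPM), 1883 (blocks), 281 (run A) and 950 (without the library with conflicting labels). Compound by time gave 6893 (library totals), 6015 (blocks) and 2512 (run A). Of 134 list calls 8 held with an estimated correlation. The correlation of 500 nM dBET6 with JQ1 was 0.27 (filter at 5 CPM), 0.29 (only the groups) and 0.272 (genes at 5 CPM) at 4 h and 0.113 without the 2 samples at 18 h. Between doses it was 0.732 (no filter), 0.991 (filter at 5 CPM) and 0.991 (genes at 5 CPM) at 4 h and 0.783 (no filter) at 18 h. Between times it was 0.639 (no filter) and 0.718 (filter) for 500 nM dBET6, and 0.562 (no filter), 0.684 (only the groups), 0.624 (run B) and 0.606 (without the 2 samples) for JQ1.

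Most results kept direction and side of the threshold. All 22 counts and correlations stayed within 1.5 times or the spread with RLE factors and without the run with epithelial transcripts. Of 819 changes of named genes, 801 were the same with RLE factors (11 lost their call, 7 gained one), 793 with limma-voom (17 lost, 9 gained), 776 with DESeq2 (4 lost, 38 gained), 760 with experiments as blocks (59 gained) and 697 with library totals (49 lost, 57 gained). Leaving out 1 sample, 16655 were the same, 430 lost and 111 gained. Of 403 list tests, 399 were the same with RLE factors (4 lost), 391 with blocks (4 lost, 8 gained), 388 with library totals (7 lost, 8 gained) and 309 with fry (44 lost, 50 gained). Leaving out 1 sample, 8194 list tests were the same, 101 lost and 154 gained.

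Leaving out 1 sample at a time, the counts ran from 1607 to 3967 (100 nM dBET6, 4 h), 2233 to 4788 (500 nM, 4 h), 189 to 988 (JQ1, 4 h), 5198 to 8240 (100 nM, 18 h), 8242 to 9769 (500 nM, 18 h) and 1119 to 2967 (JQ1, 18 h). They ran from 2294 to 4964 and 8686 to 10109 between compounds at 4 and 18 h, 0 to 0 and 0 to 1655 for dose, 2221 to 4149, 4276 to 6426 and 140 to 999 over time for 100 nM, 500 nM and JQ1, 2641 to 5050 for compound by time, and 124 to 143 for lists. For dose at 18 h the count was 244 and 318 without the control of 13E and 13F, 301 and 327 without the 4 h JQ1 sample of 13E and 13F, 311 without the 18 h JQ1 sample of 13E and 926 without the 500 nM sample of 13F. With library totals the log2 change after 18 h of 500 nM dBET6 had the other sign for BRD2 (-1.46), HEXIM1 (-1.66), MCL1 (-1.37), BCL2 (-1.56), E2F1 (-1.51), ACTB (-0.07) and PDIA4 (-0.41), and at 100 nM for ACTB (-0.18). So it had against JQ1 at 18 h for POU2AF1 (-0.73), CCND2 (-1.63), TNFRSF17 (-1.40) and BRD2 (-1.71), and over time at 500 nM for IRF4 (-0.07), HEXIM1 (-0.29), GAPDH (-0.05) and ACTB (-0.58). Leaving out 1 sample, KRT18 ran from -0.33 to 5.32 against the control and KRT8 from -0.09 to 6.47 and KRT18 from -0.36 to 5.31 against JQ1 after 4 h of 500 nM dBET6, negative without the 500 nM sample of 13F.

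Lists also changed direction for dose at 4 h: heat shock (adjusted p = 0.0181), proteasome (0.0175) and mitochondrially encoded transcripts (0.746) without the 100 nM sample of 13D, ribosome biogenesis (0.686), G1/S (0.0339) and ribosomal proteins (0.131) without that of 13F, G1/S (0.0178) and ribosomal proteins (0.0139) without the 500 nM sample of 13D, and heat shock (0.0452) and proteasome (0.011) without that of 13F. Over all samples left out in turn, adjusted p for dose at 4 h ran from 0.00271 to 0.991 for heat shock, 0.00078 to 0.728 for the proteasome, 0.00215 to 0.746 for mitochondrially encoded transcripts, 2.62e-13 to 0.895 for ribosome biogenesis, 2.03e-06 to 0.766 for G1/S and 2.83e-10 to 0.131 for ribosomal proteins. For dose at 18 h the lists were NF-kB (0.0209) and the respiratory chain (0.765) without the 100 nM sample of 13F, and mitochondrially encoded transcripts without the 500 nM sample of 13F (0.97) or the 2 samples (0.952). Their ranges were 0.0209 to 0.994 for NF-kB, 2.92e-08 to 0.765 for the respiratory chain and 1.47e-06 to 0.97 for mitochondrially encoded transcripts. Over time under JQ1 they were ribosomal proteins without the 18 h JQ1 sample of 13D (0.00393) or the 2 samples (0.00644), with a range from 4.22e-06 to 0.651. Depth limits transcripts with 0 to 3 counts in a group, given as bounds or with a counting interval.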

Other observations

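The test of gene span was planned, and no test in this part was chosen only after the result was seen. Nuclear genes of the respiratory chain rose with dBET6 in 6 of 30 cases after 4 h of 500 nM (8 over the list alone, median 0.63, adjusted p = 0.000497, adjusted p = 0.807 with an estimated correlation) and 22 after 18 h (22 over the list alone, median 1.52, adjusted p = 5.59e-05, adjusted p = 0.791 with an estimated correlation). Under library totals the 18 h median was -0.14. After 18 h of JQ1 2 fell (2 over the list alone, median -0.12, adjusted p = 0.578). After 4 h of 500 nM dBET6, 10 of 23 cell cycle inhibitors were lower than after JQ1 and 1 higher (12 and 1 over the list alone, median -0.90, adjusted p = 0.00312, adjusted p = 0.417 with an estimated correlation). Of 26 p53 targets 10 fell and 2 rose after 4 h of 500 nM dBET6 (10 and 3 over the list alone, median -0.71, adjusted p = 0.0194, adjusted p = 0.765 with an estimated correlation).

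Of 23 cholesterol synthesis genes 5 fell and 1 rose after 18 h of JQ1 (8 and 1 over the list alone, median -0.60, adjusted p = 0.0119, adjusted p = 0.724 with an estimated correlation). SQLE fell by 2.12, with a call lost without the control of 13F (adjusted p = 0.0811) or the JQ1 sample of 13D (0.0809) or 13E (0.0991). After 18 h of 500 nM dBET6 8 fell and 4 rose (8 and 4 over the list alone, median -0.07, adjusted p = 0.769). Of 31 autophagy and lysosome genes 3 rose and 1 fell after 18 h of JQ1 (1 and 0 over the list alone, median 0.49, adjusted p = 0.00576, adjusted p = 0.696 with an estimated correlation), and under 500 nM dBET6 14 rose and 8 fell (14 and 8 over the list alone, adjusted p = 0.114). Interferon genes did not pass as a list after 18 h of JQ1 (3 of 28 rose and 3 fell, 3 and 5 over the list alone, adjusted p = 0.419), although IRF7 (2.99) and STAT2 (2.12) rose, nor after 500 nM dBET6 (7 and 7, 6 and 7 over the list alone, adjusted p = 0.615). In the heat shock list HSPA8 fell by 3.50 after 18 h of 500 nM dBET6, where 2 of 20 rose and 4 fell (2 and 3 over the list alone, adjusted p = 0.647).

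ATF4 targets did not pass as a list after 18 h of 500 nM dBET6 (6 of 22 rose and 5 fell, 5 and 5 over the list alone, median 0.61, adjusted p = 0.349) or of JQ1 (7 fell, 7 over the list alone, adjusted p = 0.12). Genes of the CRL4-CRBN ligase that dBET6 needs fell in 10 of 20 cases after 18 h of 500 nM dBET6 with 3 rising (10 and 3 over the list alone, median -0.79, adjusted p = 0.357), CRBN itself at -0.89 with adjusted p = 0.0431. That call was lost without the 500 nM sample of 13F (-0.55, adjusted p = 0.137), without any 1 control (adjusted p = 0.075 to 0.0933), without any of 5 other single samples (adjusted p = 0.0541 to 0.0711) and with DESeq2 (-0.58, adjusted p = 0.176). Of 11 CRL2-VHL genes 4 fell and 2 rose (4 and 2 over the list alone, adjusted p = 0.441), of 10 COP9 signalosome genes 2 fell and 3 rose (2 and 3 over the list alone, adjusted p = 0.815), and of 38 proteasome genes 10 fell and 13 rose (10 and 13 over the list alone, adjusted p = 0.615). Of 8 long noncoding RNAs 5 rose (5 over the list alone, median 2.02, adjusted p = 0.0771), NEAT1 by 2.31.

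Of the panel genes not described so far, CCND2 (-0.73, 95% interval -1.67 to 0.20) and BCL2 (0.13, -1.03 to 1.30) did not pass after 18 h of 500 nM dBET6, whereas SERPINI1 (1.96), GAPDH (1.95) and ACTB (1.67) rose. CCND2 was lower than the control in each of the 3 experiments, and library totals place it further below. Under library totals SERPINI1 was at 0.25, GAPDH at 0.26 and ACTB at -0.07, and none of the 3 passed.

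Markers of other cells were low in MM.1S controls and some rose after 18 h of 500 nM dBET6. All 5 measured myeloid markers rose (5 over the list alone, median 6.34, adjusted p = 0.00121, adjusted p = 0.456 with an estimated correlation), LYZ from 0.114 to 122 ± 52 CPM and MPO from 0 counts, at least 276-fold. Of 7 stromal markers 5 rose (5 over the list alone, median 2.38, adjusted p = 0.013, adjusted p = 0.627 with an estimated correlation), and of 6 epithelial markers 3 (3 over the list alone, median 2.71, adjusted p = 0.0681). Of 4 T cell markers 2 rose (2 over the list alone, median 1.05, adjusted p = 0.211), whereas after 18 h of JQ1 2 fell (3 over the list alone, median -1.88, adjusted p = 0.013, adjusted p = 0.387 with an estimated correlation). The marker medians after 18 h of 500 nM dBET6 hold under TMM factors. Library totals place them lower, by values not given here, so the rises depend in part on the scaling. HBB, the measured gene of the erythroid list, stood at 12.6 ± 1.77 CPM after 18 h of 500 nM dBET6 and 0.328 ± 0.253 CPM after 18 h of JQ1, against 3.38 ± 0.186 CPM in the control. After 4 h of 500 nM dBET6 5 of 6 epithelial markers rose (5 over the list alone, median 4.69, or 4.20 with genes at 0 control counts at their bound, adjusted p = 0.0196, adjusted p = 0.626 with an estimated correlation), and without the sample of 13F the list had adjusted p = 0.196. The 3 of 7 stromal markers that rose there (5 over the list alone, adjusted p = 0.0385, adjusted p = 0.72 with an estimated correlation) gave adjusted p = 0.264 without it.

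Whether the early response depends on the span of genes was asked with 4 sets of 3338 genes each. After 4 h the median log2 change of the shortest set (median span 6.83 kb) lay above that of the longest (148.08 kb) by 0.22 under 500 nM dBET6 and by 0.22 under JQ1. From shortest to longest the medians were 0.25, -0.02, -0.14 and 0.03 under 500 nM dBET6 and 0.17, 0.05, 0 and -0.05 under JQ1. In the shortest and longest sets 665 and 380 genes fell and 269 and 173 rose under 500 nM dBET6. Under JQ1 75 and 115 fell and 72 and 37 rose. At 100 nM dBET6 the 2 medians were 0.16 and 0.03 at 4 h. At 18 h they were 0.41 and -0.63 for 500 nM dBET6, 0.28 and -0.53 for 100 nM and 0 and 0.02 for JQ1. A difference of 0.5 or more after 4 h of 500 nM had been set for a dependence and one under 0.2 against it, so for the early response it stays undecided for both compounds.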
